A study of Nomascus leucogenys and Hoolock leuconedys and Nomascus gabriellae with 23 samples.

How the data were processed

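Genomic DNA from blood of 23 gibbons was sheared and sequenced as whole-genome Illumina libraries, per the labels' protocols. BWA is named as a tool in the submitters' processing notes, with no version. The insertion caller, its filters, the genome build and the gene annotation are not given in the sources used here. The authors deposited a table of LAVA sites with a call for each site and animal, in which 1 marks a carried insertion, 0 marks an insertion that is not carried and NA marks a missing call. The table holds no genotypes, qualities or read numbers, so the sequencing depth per animal is unknown and no call can be weighted by it. Each site also has a position, an element length, a position on a LAVA consensus, a location class relative to a gene, an orientation and a human Ensembl gene name, per the file headers and values.

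The deposited table lists 5490 sites on 26 chromosomes, each carried by at least 2 animals. Sites take 2 forms. At 4372 sites the position spans a single base, and at 1118 sites it spans the whole length of the element. They are called single-base sites and interval sites here. That interval sites are elements present in the reference assembly is an inference from these values and is stated by no source. N. leucogenys replicate 1, which carried all 1118 interval sites, is labelled Asia.NLE, the name in the RefSeq assembly Asia_NLE_v1 used below. Most gene positions did not match that assembly, so the build stays unknown and the inference is not settled. Interval sites are 540 to 6352 bp long and single-base sites 291 to 1839 bp, so the 2 forms have different lower length limits. Missing calls made up 0.712% of the table (899 of 126270), and 4962 sites had none.

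Animals were grouped by the species in the labels and, above that, by genus: 13 Nomascus, 5 Hylobates, 3 Hoolock and 2 Symphalangus. Replicates are numbered by order of deposit within a species and the numbers pair nothing. All 23 columns of calls were matched to an animal by its label. Whether the animals are related to each other is not given in the sources used here, so p-values describe these animals and treat them as independent.

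Missing calls were treated as not carried. Sites per animal were compared between the 6 pairs of genera with exact two-sided permutation tests of the difference in means, and the 10 pairs of species with at least 2 animals in the same way. Benjamini-Hochberg adjustment was applied within each family and the threshold was an adjusted p of 0.05. A site was assigned to a genus if at least 1 of its animals carried it. Similarity between animals was the Jaccard index, the number of sites carried by both over the number carried by either, tested with 10000 permutations of the genus labels. Each site was tested for a difference in carriers between Nomascus and the other genera with a two-sided Fisher's exact test, adjusted over all sites. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Simulated data for the comparison of Nomascus with the other genera held 5490 sites, of which 200 were changed. Of these, 196 were recovered, and 1 unchanged site was called. Animals were simulated as independent, and changed sites were carried by nearly all animals on 1 side and by few on the other. Recovery of weaker differences or of sites of a single genus, and false calls among related animals, were not measured.

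A site was counted as in a gene if its class was intronic, exonic or untranslated region. The design fixed before the data were examined also counted upstream sequence. The window of the deposited promoter class is not given in the sources used here, so that class is a separate one in the main setting and is added in an alternative. Comparison with random placements and gene-length matching needed an annotation of the same build and were not run. Gene names were looked up in the RefSeq gene table of assembly Asia_NLE_v1 for names and gene type only. Of 2607 gene names, 1881 were found there and 1879 were protein-coding. Of 2312 sites with a matched name, 71 lay within 1 kb of that gene's position in the RefSeq table, so none of its coordinates or lengths are used. A gene name in the deposited table had been turned into a date and is not used by name.

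The 6 gene lists, the tests named above and the rule for named genes were fixed before the data were examined. The rule takes up to 8 members per list by number of sites, the 10 genes with the most sites, up to 8 genes per genus with a site carried by all animals of that genus and no other animal, and up to 8 genes with a site carried by all 23 animals in an exon or promoter. Some genes taken by the rule are not reported here. For the genus and all-animal parts, exonic and untranslated sites come first, then chromosome and position. Other choices came after the data had been explored by site form, length, sharing and location: the comparison of interval with single-base sites, the 540 bp length limit, the comparisons among genus-specific sites, the share of the smaller set as a measure of similarity, and the tests of sharing and orientation within gene lists. The design also held no separate tests of introns, promoters, terminators or untranslated regions. Nor did it compare orientation between sets of sites, or test it outside introns. The p-values of all of these are to be read as those of tests chosen after seeing the data. Alternatives covered missing calls, site form, merging of sites within 100 bp, autosomes, single animals left out, equal numbers of animals per genus, the definition of presence, the similarity measure and the gene set. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.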

Results

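The study examined LAVA, a composite retrotransposon found in gibbons and built from parts of other repeats (a LINE fragment, an AluSz element, a variable number of tandem repeats and an Alu-like part). Blood DNA of 23 gibbons from 4 genera was sequenced. Nomascus was represented by 11 N. leucogenys and 2 N. gabriellae. Hylobates was represented by 2 H. moloch and by 1 animal each of H. lar, H. muelleri and H. pileatus. Hoolock was represented by 3 H. leuconedys and Symphalangus by 2 S. syndactylus. The measurement is whether an animal carries LAVA at each of 5490 sites, and the sequencing depth behind the calls is unknown.

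The first comparison asked how many LAVA sites an animal of each genus carries. Hoolock animals carried the most, 2807 ± 88.6 sites (SD, n = 3). Symphalangus animals carried 2271 ± 4.95 (SD, n = 2), Hylobates animals 2214 ± 193 (SD, n = 5) and Nomascus animals 1598 ± 88.5 (SD, n = 13). The highest Nomascus animal, with 1736 sites, was below the lowest animal of any other genus, with 1995. The order came from single-base sites, of which Nomascus animals carried 484 ± 91.3 (SD, n = 13) and Hoolock animals 1829 ± 95 (SD, n = 3). At interval sites the direction was the opposite, with 1113 ± 3.99 in Nomascus (SD, n = 13), 976 ± 35.3 in Hylobates (SD, n = 5), 978 ± 9.29 in Hoolock (SD, n = 3) and 989 ± 18.4 in Symphalangus (SD, n = 2).

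In exact two-sided permutation tests adjusted over 6 pairs, Nomascus differed from Hylobates (p = 0.0007), Hoolock (p = 0.00536) and Symphalangus (p = 0.019), and Hylobates differed from Hoolock (p = 0.0268). The difference between Hylobates and Symphalangus was not past the threshold (exact permutation p = 0.762 after adjustment). Hoolock and Symphalangus cannot reach the threshold, since the smallest exact p for 3 against 2 animals is 0.1. The total per animal depends on which form is counted, and every one of the 1118 interval sites was carried in Nomascus, all of them by each of 2 N. leucogenys animals, so this form holds no site absent from the genus. Only sites with at least 2 carriers are listed, which removes sites of single animals in every genus.

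**Figure D1:**
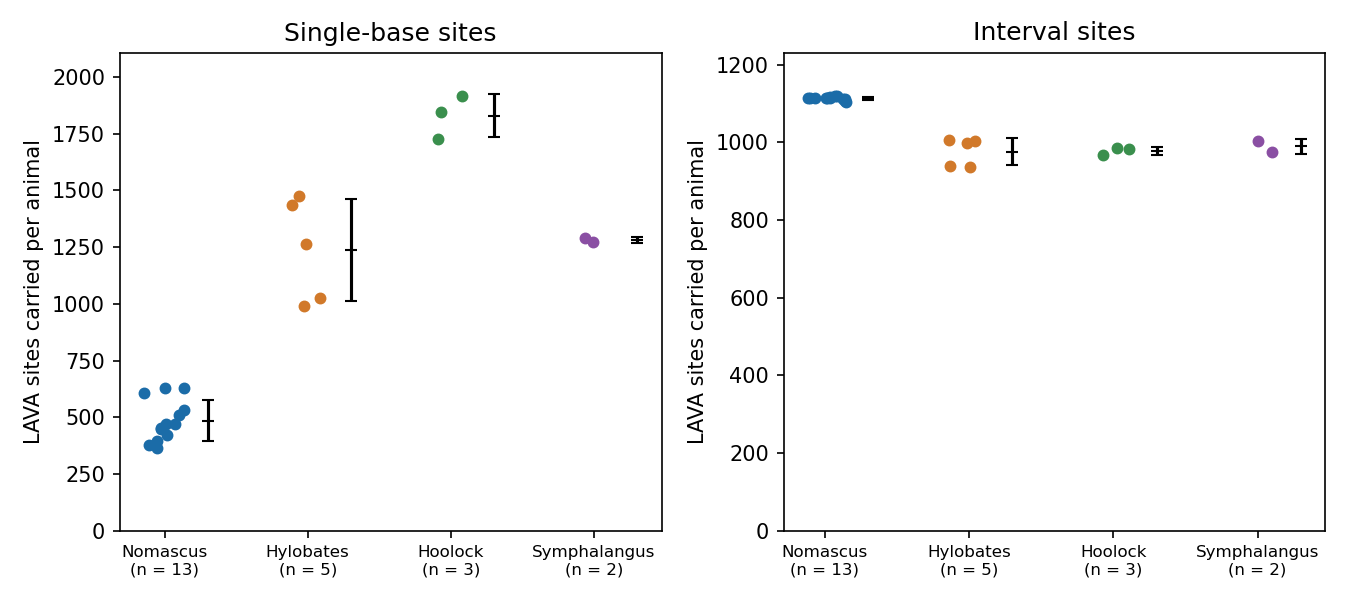
Number of LAVA sites carried by each animal (vertical axes, sites, from 0) by genus, for single-base sites (left) and interval sites (right); points are animals, and the bars beside them are the mean and SD. Nomascus animals carry 363 to 629 single-base sites, below all other animals, and 1104 to 1118 interval sites, above all other animals.

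Within Nomascus, N. gabriellae carried more listed sites than N. leucogenys. The 2 N. gabriellae carried 1734 ± 3.54 (SD, n = 2) and the 11 N. leucogenys 1573 ± 71.0 (SD, n = 11), and both N. gabriellae lay above the highest N. leucogenys, which carried 1722. The difference was again at single-base sites, with 628 ± 1.41 against 458 ± 71.6. The exact two-sided permutation test gave an adjusted p of 0.0321 over 10 species pairs. Its unadjusted p of 0.0128 is the smallest that the 78 assignments can give. The difference of 160 sites shrank at 540 bp and above, a limit chosen after seeing the data, and stayed past the threshold there. At interval sites N. gabriellae was the lower of the pair, with 1106 ± 2.12 against 1115 ± 2.05. The direction thus depends on the form counted, and how the authors found the 2 forms is not given in the sources used here. Whether the species differ in their number of LAVA insertions cannot be told from these counts.

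The second comparison asked which insertions the genera share. Of the 5490 sites, 1374 (25%) were carried in all 4 genera and 916 by all 23 animals, of which 906 were interval sites. A further 2873 sites (52.3%) were carried in a single genus, 705 in 2 genera and 538 in 3. Hoolock had 1167 genus-specific sites, Hylobates 828, Symphalangus 526 and Nomascus 352. In Hoolock, 948 of these were carried by all 3 animals, in Hylobates 192 by all 5 and in Nomascus 17 by all 13. Every Symphalangus-specific site is carried by both animals, because listed sites have at least 2 carriers. At 540 bp and above, a limit chosen after seeing the data, genus-specific sites numbered 1003 in Hoolock, 490 in Hylobates, 435 in Symphalangus and 199 in Nomascus. The single-base site is the only form of the sites specific to Hylobates, Hoolock or Symphalangus, whereas all 17 Nomascus sites carried by every animal of the genus were interval sites.

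Named genes held sites of each kind. The 17 Nomascus-specific sites carried by all 13 animals include 6 in genes, all intronic, in AL589740.1, ADAM10, NEK1, NRG1, ST5 and MAD1L1. ADAM10 encodes a membrane metalloprotease, and its site lay on chromosome 6 from 77733574 to 77734982, antisense to the gene. MAD1L1 encodes a spindle checkpoint protein, and its site lay on chromosome 20 from 2090551 to 2092425, antisense. NRG1 encodes a growth factor of the neuregulin family, and its site lay on chromosome 8 from 37271607 to 37272263, antisense. Coordinates are those of the deposited table counted from 1, on a build not given in the sources used here.

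Sites carried by all 5 Hylobates and no other animal included 2 in the deposited 3' untranslated class, named GAS1RR and the kinase gene CDKL1 (chromosome 1a, 82234958, 1838 bp, sense). The intronic sites next in order included those in TEX10, C9orf3, NEMF and SUSD6. Of the Hoolock-specific sites carried by all 3 animals, 464 were in genes and 10 were classed as exonic or untranslated. The first 8 of these by position were in AC093206.1, AL138737.1, AC008121.2, ZNF726, VSIG10, DEFB132, LHFPL3-AS1 and PXDNL. The site in the 3' untranslated region of PXDNL was 1837 bp long and lay on chromosome 16 at 42224109. The Symphalangus-specific sites had 300 in genes, of which 5 were in a deposited untranslated class, under the names SNHG5, GABPB1-AS1, PSMD4, THY1 and LINC01756. GAS1RR, LHFPL3-AS1, SNHG5, GABPB1-AS1 and LINC01756 are names of non-coding RNA genes. Such genes have no untranslated regions, so the class cannot be read that way for them. PSMD4 encodes a ubiquitin receptor of the proteasome, and its 3' untranslated site lay on chromosome 12 at 50923137. THY1 encodes a cell surface glycoprotein, and its 5' untranslated site lay on chromosome 15 at 15762354. The next sites in order were intronic, in KANK1, PLGRKT and the phosphatase gene CDC14B.

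Among sites carried by all 23 animals, 1 was classed as exonic, in STAG3L5P-PVRIG2P-PILRB, a readthrough gene (chromosome 17, 35368233 to 35369535, 1303 bp, sense). The promoter sites next in order were those of AL133163.3, PRELID2, RN7SKP118, DNAH3, ARHGAP19, AP001107.3 and RNA5SP25. DNAH3 encodes an axonemal dynein heavy chain and its promoter site, 1956 bp long, lay in sense orientation on chromosome 2 from 88802108 to 88804063.

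Animals of the same genus shared more sites than animals of different genera. The mean Jaccard index was 0.743 within genera and 0.421 between them. Hoolock had mean indices of 0.362 with Hylobates, 0.367 with Symphalangus and 0.369 with Nomascus, and Nomascus had 0.457 with Hylobates and 0.452 with Symphalangus. The Jaccard index falls as sets differ in size, and Hoolock sets were the largest. As a share of the smaller set, a measure chosen after seeing the data, Nomascus shared 74.5% with Hoolock, 74.7% with Hylobates and 75.5% with Symphalangus, so Hoolock did not stand apart from Nomascus by this measure. By the same measure Hoolock shared 60.5% with Hylobates and 60.0% with Symphalangus, and Hylobates shared 62.4% with Symphalangus. In pairs with Nomascus the smaller set was always the Nomascus animal. Nomascus animals carried 1598 sites on average, of which 1113 were interval sites, a form with no site absent from the genus. Shares with Nomascus rest largely on that form and cannot be compared with those of the other pairs. Within Hylobates the mean was 0.652 over 10 pairs, the lowest within-genus mean. Only 1 of these pairs was of the same species, H. moloch (0.718), whereas Hoolock and Symphalangus hold 1 species each. Pairs of N. gabriellae with N. leucogenys had a mean of 0.728, against 0.761 within N. leucogenys. The ranking of genera therefore compares different mixes of species. Hylobates moloch replicate 1 shared more with H. muelleri replicate 1 (0.776) than with H. moloch replicate 2 (0.718). The difference of 0.322 between the within-genus and between-genera means gave p = 0.0001 in a two-sided permutation test, the smallest that 10000 permutations can give.

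**Figure D2:**
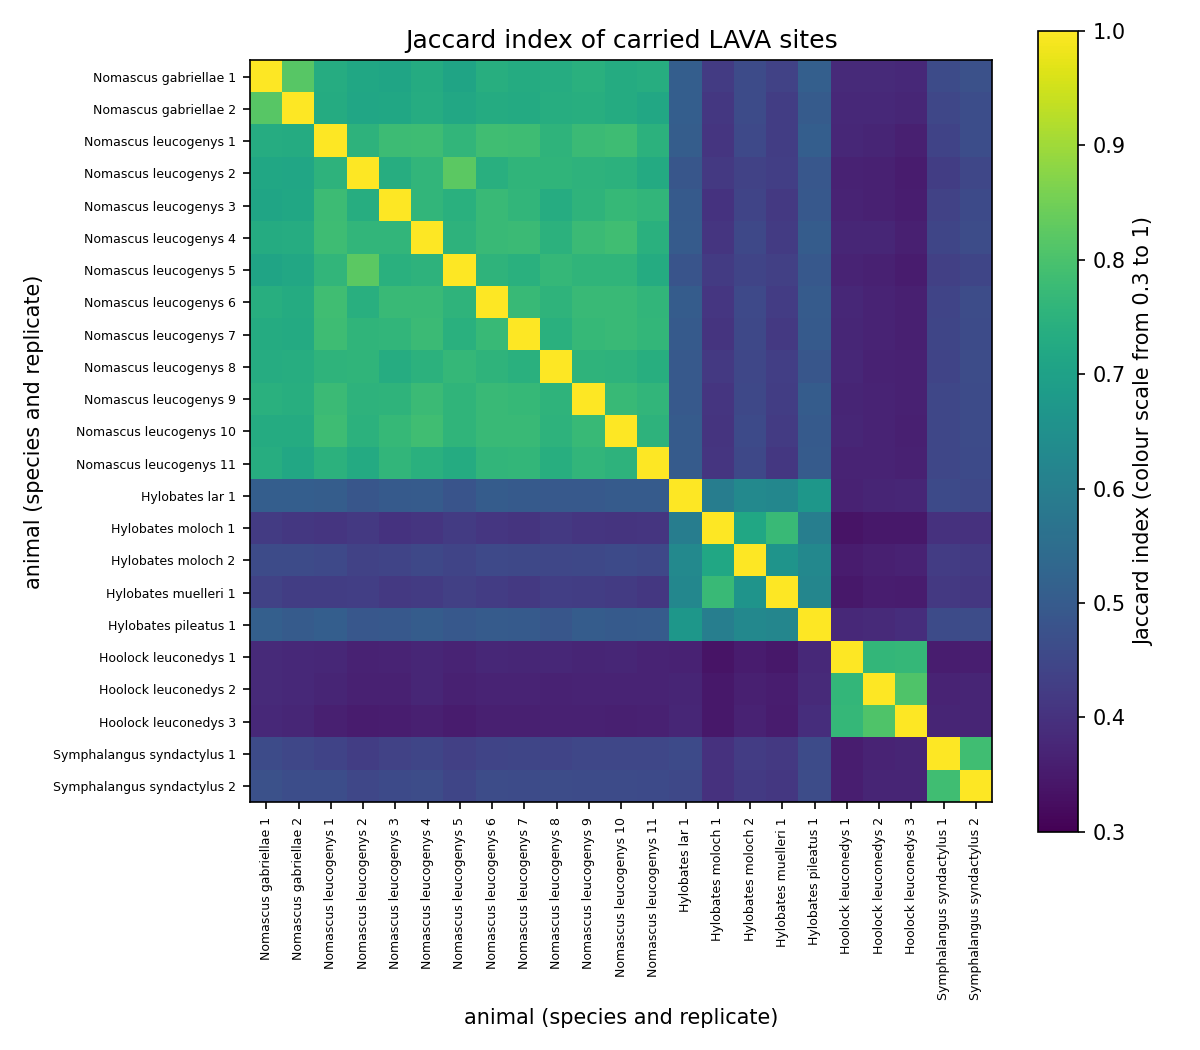
Jaccard index of carried LAVA sites for every pair of the 23 animals (rows and columns, by species and replicate), on a colour scale from 0.3 to 1. Blocks of higher index follow the 4 genera, with means of 0.753 in Nomascus, 0.652 in Hylobates and 0.779 in Hoolock, and 0.786 for the Symphalangus pair.

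The third comparison asked which sites differ in frequency between the 13 Nomascus and the 10 other animals. At 165 sites carriers were more frequent in Nomascus and at 263 less frequent, 428 of 5490 in all by Fisher's exact test with Benjamini-Hochberg adjustment. Of the 165, 136 were interval sites, and all 263 were single-base sites. Each Nomascus animal carried 1104 to 1118 of the 1118 interval sites, which leaves almost no room for a lower frequency in Nomascus. By Fisher's exact test 0 interval sites were less frequent there, even at an unadjusted p under 0.05. The direction at interval sites was thus set by the form and says nothing about the genera. In genes lay 76 of the former and 144 of the latter. Of the 263 sites less frequent in Nomascus, 156 were carried in all 3 other genera and in no Nomascus animal. At 540 bp and above, a limit chosen after seeing the data, 157 sites were more frequent and 123 less frequent, so the balance of directions depends on short sites. Sites carried only in Hoolock or only in Symphalangus cannot pass the threshold, since their smallest unadjusted p is 0.0678 and 0.178. Sites carried only in Hylobates were not called either, with a smallest unadjusted p of 0.00749 and a smallest adjusted p of 0.0545, so none of the 263 is specific to 1 genus. The 192 sites carried by all 5 Hylobates and no other animal share these p-values, just above the threshold. That none of the 263 is specific to 1 genus therefore hangs on the threshold. The number of less frequent sites rose to 470 to 481 when any 1 Hoolock or Symphalangus animal was left out. With fewer other animals, those 192 sites have a lower p at the same carriers. The rise can thus come from the threshold, and which sites were added was not listed.

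Within N. leucogenys, 2266 sites were carried by at least 1 of the 11 animals. All 11 carried 1139 of them, 50.3% (95% interval 48.2 to 52.3), of which 1102 were interval sites. A single animal carried 208, 9.18% (95% interval 8.02 to 10.4), each of which has a carrier in another species because sites with 1 carrier are not listed. The remaining 919 sites (40.6%) were carried by 2 to 10 animals. By form, 98.6% of interval sites and 3.22% of single-base sites carried in the species were carried by all 11, and 2 of the 11 animals carried every interval site.

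The next comparison asked where LAVA lies relative to genes. Introns held 2745 sites, intergenic sequence 2347 (42.8%), terminator sequence 179, promoter sequence 173, 3' untranslated regions 36, 5' untranslated regions 9 and exons 1. Sites in genes made up 50.8% (95% interval 49.5 to 52.2). Sites carried in all 4 genera were in genes at 49.3% and sites of a single genus at 50.9%, a difference not past the threshold (Fisher's exact test, adjusted p = 0.406 over 5 location tests). The deposited untranslated classes include sites in non-coding RNA genes, and their test was not among those fixed beforehand. They held 1 of 1374 sites carried in all 4 genera and 30 of 2873 sites of a single genus (Fisher's exact test, adjusted p = 0.000685). Among single-base sites alone, with 403 in all 4 genera, this difference was of similar size but not past the threshold (Fisher's exact test, adjusted p = 0.42). No interval site lay in an untranslated region. Symphalangus-specific sites were in genes at 57.0%, against 49.3% for Hoolock (adjusted p = 0.0195), 50.1% for Hylobates (adjusted p = 0.042) and 49.1% for Nomascus (adjusted p = 0.0455), by Fisher's exact test over 6 pairs.

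Intronic LAVA lay more often antisense to the gene than in sense orientation. Of 2745 intronic sites, 1054 (38.4%, 95% interval 36.6 to 40.2) were in sense orientation, which differs from 50% in a two-sided exact binomial test (p = 3.34e-34). Promoter sites were 51.4% sense and terminator sites 47.5%, and neither departure from an even split was past the threshold (adjusted p = 0.951 and 0.917). Of intergenic sites, 49.2% were on the plus strand. The bias was present at both forms of site, 25.6% sense among 543 interval sites and 41.6% among 2202 single-base sites, and these shares differed (Fisher's exact test, adjusted p = 1.21e-11 over 4 tests). In the same family, sites in all 4 genera were 32.7% sense and sites of a single genus 38.2% (adjusted p = 0.0176), but 971 of the 1374 sites in all 4 genera are interval sites. Among single-base sites of at least 540 bp the direction turned, with 46.7% against 36.4% (Fisher's exact p = 0.0542). Among genus-specific sites the sense share was 35.5% in Hoolock, 36.9% in Symphalangus, 41.0% in Hylobates and 42.4% in Nomascus, and no difference between 2 genera was past the threshold (lowest adjusted p = 0.314 over 6 pairs).

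**Figure D3:**
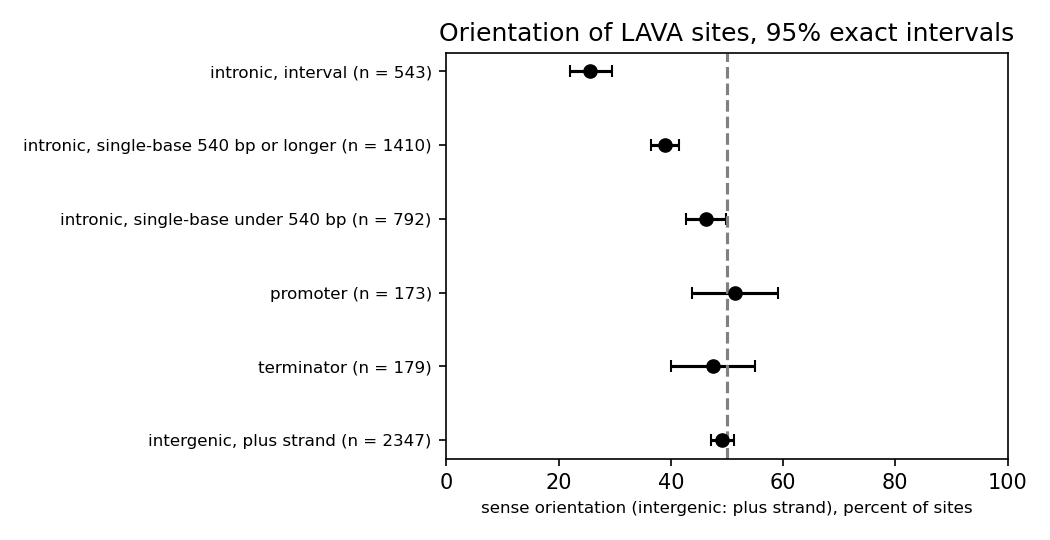
Share of LAVA sites in sense orientation relative to the gene, or on the plus strand for intergenic sites (horizontal axis, percent of sites), with exact 95% intervals; the dashed line marks 50%. Intronic interval sites have the lowest share, 25.6%, and promoter, terminator and intergenic sites include 50% in their intervals.

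The gene lists were used to describe which genes hold LAVA in their body. The gene names with the most sites were NEMF and USP32 with 6 each, followed by EXOC6B, FHIT, STAG3L5P-PVRIG2P-PILRB and TYW1B with 5. Next were 5S_rRNA, AC233280.6, AGBL1 and COMMD1 with 4, among 14 genes at that number. Sites named 5S_rRNA lay from 10245791 to 12121688 on chromosome 14, and those named AC233280.6 from 121058746 to 123124102 on chromosome 11. Sites named STAG3L5P-PVRIG2P-PILRB, among them the only site classed as exonic, lay from 34699176 to 35369535 on chromosome 17. Whether any of these names marks a single gene body on this build could not be checked. NEMF encodes a factor of ribosome quality control. Its 6 intronic sites include 3 carried by all 23 animals, 1 specific to the 5 Hylobates animals, and a pair 28 bp apart carried by Hylobates and Symphalangus animals. USP32 encodes a deubiquitinase, and 3 of its 6 sites were carried in all 4 genera. With no annotation of the same build, no enrichment was computed for any list.

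Of 112 chromosome segregation and spindle genes, 25 held 35 sites in the gene body. ESCO1, a cohesin acetyltransferase gene, and PDS5A, a cohesin regulator gene, had 3 sites each. ANAPC1, CEP164, CLASP2, KIF4A, NCAPG2 and PMF1 had 2 each, and in all of these but KIF4A 1 site was carried by all 23 animals. In CLASP2, a microtubule-binding protein gene, that site lay in sense orientation on chromosome 4 from 118869031 to 118869965. Of 123 microtubule and cilium genes, 28 held 37 sites. CEP112 and CFAP70 had 3 each, and DYNC1H1, IFT88, KIF13A, KIFAP3 and SPAST had 2. BBS9, a gene of the BBSome complex of cilia, had 1 site, carried by all 23 animals. SPAST, which encodes the microtubule-severing enzyme spastin, had 1 site in Hylobates and 1 in Symphalangus.

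Of 137 DNA repair genes, 18 held 22 sites. MRE11 had 1 site carried by the 5 Hylobates animals and 1 by both Symphalangus animals, and RAD17 had 2 sites. ATRIP, BRIP1 and ERCC8 each had a Symphalangus-specific site, ERCC3 a site in 2 Nomascus animals and MSH6 a site in all 23 animals. Of 65 genes of meiosis and germline transposon silencing, 6 held 8 sites. MORC1 and TDRD12 had 2 each, and HORMAD2 and TDRD5 each had a site carried by all 23 animals. MPHOSPH8, of the HUSH silencing complex, had a Symphalangus-specific site, and TEX14 had a site in 3 animals.

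Of 96 synapse and cell adhesion genes, a comparison list of long genes, 34 held 60 sites. FHIT had 5 sites, RBFOX1 4, and CNTN4, CSMD3, DCC, GRIK2 and WWOX 3 each. Of the 60 sites, 4 (6.67%) were carried in all 4 genera, against 24.3% of all sites in genes (Fisher's exact test against the other genes, adjusted p = 0.00383 over 6 lists). In the other 5 lists the test did not pass the threshold, with shares of 37.1% in the segregation list, 27.0% in the microtubule list, 40.9% in the repair list, 37.5% in the meiosis list and 0 of 2 sites in the ribosomal list. The difference from other genes was -18.0 percentage points over all sites. It was -58.0 among interval sites alone (adjusted p = 0.000256), -20.5 at 540 bp and above (adjusted p = 0.0283) and -7.24 among single-base sites alone, where it was not past the threshold (adjusted p = 0.495). Of 76 ribosomal protein genes, a comparison list of short genes, 2 held a site, RPL19 and RPS24. The intronic sense share was past the threshold against other genes in no list (Fisher's exact test, adjusted p = 1 for every list).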

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

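The comparisons of genus-specific sites and of the 2 site forms were chosen after the data had been explored, as were the tests below of animal numbers, short calls, strand, length and insertion age. The test of absence calls at interval sites was set before its result was seen.

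Symphalangus-specific sites lay in genes more often than those of the other genera, which differed by -7.76 percentage points for Hoolock, -7.89 for Nomascus and -6.91 for Hylobates. The difference from Hoolock was past the threshold without missing calls and without sites under 540 bp.

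Hoolock had the most genus-specific sites, and Nomascus had only 17 carried by all its animals. Unequal animal numbers may contribute to the 17, since in 100 draws of 2 animals per genus, both required to carry a site, the Nomascus count was 82 (51 to 143), but they are not the whole cause: it was at most 0.475 times that of any other genus, and the Hoolock count was at least 1.80 times the Symphalangus count. Short calls are not the whole cause of the Hoolock count, which was 2.05 times that of the next genus at 540 bp and above. For the few Nomascus sites, under-called absence at interval sites remains open: of 132 interval sites lacked by at least 2 Hoolock animals, 52.3% were lacked by all 3, against 81.2% of Hoolock-specific sites carried by all 3. True polymorphism of these sites in Hoolock may give the same value, and a difference between the genera themselves is untested. The draws used the same listed sites, so they cannot test how the authors found and filtered the 2 forms. All 17 sites were interval sites, and of the 1139 sites carried by all 11 N. leucogenys only 37 were single-base sites.

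Intronic interval sites were in sense orientation less often than single-base sites, by -16.0 percentage points. The lack of short interval sites could not be the whole cause, since at 540 bp and above single-base sites still exceeded interval sites by 13.3 percentage points (Fisher's exact p = 2.57e-08). A bias of the calls towards 1 genome strand, if alike inside and outside genes, can move the sense share no farther from 50% than the plus-strand share of intergenic sites (49.2%), and by 95% intervals the intronic departure exceeded this by at least 3.46 percentage points in both forms. Insertion age may contribute but cannot be told apart: over all intronic sites the sense share in all 4 genera differed from that of 1 genus by -5.43 points (adjusted p = 0.0176), the direction needed, but most sites in all 4 genera are interval sites, and among single-base sites of that length it was 10.3 percentage points higher, on 90 against 1048 sites (Fisher's exact p = 0.0542). How the authors found and filtered the 2 forms stays open.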

How the results depend on the processing

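Settings for site length, single Nomascus animals left out, the overlap of the smaller set, promoter and terminator sites, and site form in genes, lists and species were chosen after seeing the data. Every interval site is carried in Nomascus, so values at these sites cannot show one absent from it. At interval sites only, the difference in sites per animal turned to 137 for Nomascus minus Hylobates, 136 minus Hoolock and 124 minus Symphalangus, to -11.3 for Hoolock minus Symphalangus and to -9.23 for N. gabriellae minus N. leucogenys, and Hylobates minus Hoolock was -1.67. There, 19 sites were specific to Nomascus and 0 to Hylobates, 0 to Hoolock and 0 to Symphalangus, 0 sites were less frequent in Nomascus by Fisher's exact test (0 at an unadjusted p under 0.05), 98.6% were carried by all 11 N. leucogenys and 0% by 1, and 48.7% lay in genes. At single-base sites only, 403 were carried in all 4 genera, 29 were more frequent in Nomascus, 3.22% were carried by all 11 N. leucogenys and 18.1% by 1. The untranslated-region difference was then -0.803 points and the synapse list difference -7.24 points, neither past the threshold, while the latter was past it at interval sites (-58.0) and at 540 bp and above (-20.5).

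Without N. leucogenys, Nomascus minus Hylobates was -480.3, minus Hoolock -1073 and minus Symphalangus -537, and Hylobates minus Hoolock -592.9, with no pair past the threshold. The last difference is unchanged and lost its call through the adjustment. Leaving out 1 animal at a time gave -642 to -538 for Hylobates minus Hoolock, past the threshold except without any 1 Hoolock animal. It gave -684 to -663 for Nomascus minus Symphalangus, past it except without either Symphalangus animal (-676 and -669), where the exact test has too few assignments. For N. gabriellae minus N. leucogenys it gave 151 to 175, past it except without N. gabriellae replicate 1 (163) or 2 (158), where a single animal remains. Sites less frequent in Nomascus ranged from 220.0 to 481.

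Counting a genus only where all its animals carry a site gave 124 sites in Nomascus alone and 227 in Hylobates alone, some with carriers in part of another genus. By the main rule of at least 1 carrier, sites of 540 bp and above numbered 199 specific to Nomascus and 490 specific to Hylobates. At that length, 157 sites were more frequent in Nomascus and 123 less frequent, which turns the balance. The N. leucogenys shares there were 68.1% for all 11 and 6.27% for 1, and 1 ribosomal gene held a site. Differences in sites per animal shrank there to -282 for Nomascus minus Hylobates, -439 minus Symphalangus and 69.4 for N. gabriellae minus N. leucogenys, all past the threshold, while Hylobates minus Hoolock grew to -657 and Hylobates minus Symphalangus from -56.7 to -156 (adjusted p = 0.1). Without missing calls, 53.0% were carried by all 11. In genes lay 54.0% with promoter sites and 39.0% with protein-coding genes only. With 2 animals per genus, Fisher's exact test called 0 sites in each direction (median of 153 at an unadjusted p under 0.05), where the smallest p is 0.0357. With N. leucogenys cut to 2 animals it also called 0 in each direction (median of 271 unadjusted). Both designs have fewer animals, which limits the test. The difference in Jaccard index stayed between 0.0993 and 0.342 with p = 0.0001 over the site settings, and as a share of the smaller set the difference was 0.160 with the same p, the smallest the permutations can give. No paired analysis was possible because replicate numbers follow the order of deposit and pair no animals.

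Call quality, homozygous calls, other upstream windows, random placement, length matching and flanks around gene bodies were not run, for lack of such columns or a same-build annotation. Leaving out sites with 1 carrier removes nothing. Depth is unknown, so missed calls cannot be bounded.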

Other observations

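The lengths of single-base sites differed by sharing. Sites under 540 bp made up 14.1% of Hoolock-specific and 17.3% of Symphalangus-specific single-base sites, against 40.8% for Hylobates, 45.9% for Nomascus and 59.1% for single-base sites in all 4 genera. Elements of at least 1800 bp made up 36.5%, 40.5%, 21.6%, 18.3% and 5.21% of the same sets. These shares have no test and both length limits were chosen after seeing the data. N. leucogenys replicates 2 and 5 had a Jaccard index of 0.824, the highest of the 55 pairs in that species.

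The split of the animals into Nomascus and other genera gave 428 differing sites, and of 100 splits into 13 and 10 animals, the real one included, 1 gave as many. The highest of the others gave 0, so no other drawn division of these animals gave a called site. The other splits mix the genera, which were not assigned by chance. They therefore cannot test relatedness within a genus or how the sites were found, and add no support for single sites.

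Hylobates moloch replicate 1 was closer to H. muelleri replicate 1 than to H. moloch replicate 2. The tests of overlap and labels were chosen after the indices were seen, and the test of detection before its result. An exchanged label of replicate 2 stays open. Its index with replicate 1 exceeded its highest other index, 0.663 with H. muelleri, by 0.0546. After an exchange with H. muelleri, however, replicate 1 and the animal labelled H. muelleri would be the H. moloch pair. Those 2 animals had the highest index in Hylobates (0.776), so the test cannot argue against such an exchange. Higher detection in the 2 closer animals may contribute. At 3359 single-base sites with at least 2 carriers outside Hylobates, the lower of these 2 exceeded the other 3 Hylobates animals by 1.61 percentage points. The intervals of H. moloch replicates 1 and 2 overlap, however. H. moloch replicate 1 and H. muelleri also had fewer missing calls, 28 and 24 against 66 to 90 in the other 3. They carried fewer interval sites, 936 and 939 against 997 to 1005. The share of the smaller set that is shared was 1.67 percentage points higher with H. muelleri, within overlapping intervals, so the number of sites per animal cannot be told apart as a cause. H. moloch replicate 1 and H. muelleri shared 336 sites absent from replicate 2, replicate 2 and H. muelleri shared 93 absent from replicate 1, and the 2 H. moloch shared 197 absent from H. muelleri. Shared ancestry of these animals was not tested.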
